A study of Homo sapiens with 32 samples.

How the data were processed

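Antigen presenting cells, sorted by flow cytometry as live, CD45-positive, HLA-DR-positive cells carrying CD11c or CD14, were profiled from the cervix and from peripheral blood of donors whose genital bacterial community was dominated by Lactobacillus, Gardnerella or Prevotella. Per the labels' protocols, cells were sorted into TRIzol, RNA was extracted with a carrier, and libraries were made by 3′ digital gene expression, a method derived from single-cell RNA barcoding and sequencing that counts one tag near the 3′ end of each transcript. Tags from this method do not depend on transcript length. Reads were aligned with BWA to hg19, per the submitters' processing notes; versions, the annotation and the rule for counting are not given in the sources used here. The values used here are the deposited whole-number counts per gene symbol and library, not normalized; whether a count is a molecule or a read is not stated per the labels. Intervals and floors below therefore cover counting error only.

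The table held 16599 gene symbols and 32 libraries: 18 cervical (5 Lactobacillus, 8 Gardnerella, 5 Prevotella) and 14 from blood (4, 6 and 4). Each library came from a donor of its own within its site; 12 of the 20 donors gave both sites, 6 a cervical library only and 2 a blood library only. Left out were 20 symbols that had been turned into dates (0.132% of counts) and 21 symbols of XIST, TSIX and the Y chromosome, as a rule for human samples. Of the 16558 symbols kept, 14668 were found in a table of human gene names. Gene names are those of the deposited table (IL8 is CXCL8, IGJ is JCHAIN). The table held no positions and the reference annotation was of another build than hg19, so no coordinates are given.

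Total counts per library ran from 13132 to 227800, with a median of 59456. At these depths only abundant genes could be compared: after the filter of edgeR (filterByExpr by group, minimum count 10), 857 genes were tested in the cervix, 746 in blood and 1135 over both sites, holding 81.0% of cervical and 81.5% of blood counts. The duplicate check compared 75 pairs of libraries within groups: the lowest chi-square per degree of freedom was 2.58, so none agreed within sampling noise.

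Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, two-sided, TMM scaling) in R 4.3.3, with 1 mean per group and Benjamini-Hochberg adjustment at 0.05. The 3 communities were compared within each site, in a fit of all libraries of that site. The sites were compared as the average of the 3 cervical group means against that of the 3 blood group means, in a fit of all 32 libraries, which also gave the site by community terms. Levels are CPM, counts relative to the effective library size, on the scale of these fits, given as mean ± SD over libraries; log2 fold changes are given ± SE. The 31 gene lists were tested with camera of limma 3.58.1 on voom values of the same genes, with an estimated correlation between genes and adjustment over the lists with 5 or more tested members (17 in the cervix, 10 in blood, 18 over both sites); a preset correlation of 0.01 and fry were alternatives. Library measures, and sums of 14 lists of cell type markers on the log2(CPM + 50) scale, were compared with exact two-sided permutation tests, or with 100000 resamples where both groups held 10 or more libraries.

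The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names up to 6 genes with the largest rise and 6 with the largest fall at 20 CPM or more, up to 2 genes per list, the 10 genes with the smallest p where fewer than 5 pass, and a panel of 18 immune genes for the cervical communities. List members given as examples beyond these were chosen after their values were seen. Alternatives were median ratio and upper quartile scaling, DESeq2 1.42.0, limma with library quality weights, a minimum count of 3, no filter, fits of other sets of libraries, each library left out in turn, and a replicate block by donor. Added after the data were examined were a fit without the 4 libraries under 30000 counts, a comparison of Gardnerella and Prevotella together with Lactobacillus, the shares of MALAT1 and IL8, and ratios of pooled counts for genes with few counts in a blood community. The share of mitochondrial genes was not analysed here.

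The donor numbers in the labels pair the cervical and blood libraries of 12 donors. Deviations from the group means correlated with a median r of 0.0978 within these 12 pairs (-0.0724 to 0.275) and of -0.00497 over 240 pairs of different donors. The tests were tried on simulated counts with the depths of these libraries, with 200 changed genes of known fold. With many changed genes the adjustment is milder, so the shares below overstate recovery where few genes pass. The simulated cervical Prevotella comparison gave 125 calls and the real one 3. For cervical Prevotella against Lactobacillus (896 genes tested), 20.0% of genes changed 2-fold, 83.9% of genes changed 4-fold and 92.1% of genes changed 8-fold were recovered. The same shares were 28.6%, 90.6% and 100% for blood Prevotella against Lactobacillus (720 genes), 60.9%, 100% and 100% for cervix against blood (1131 genes), and 4.76%, 42.9% and 69.4% for the Prevotella site by community term (1164 genes); no recovered gene had the wrong direction.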

Results

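Transcript counts of sorted antigen presenting cells (monocytes, macrophages and dendritic cells, by the gate used) were available for 18 cervical and 14 blood libraries. The cervical libraries came from 5 donors with a Lactobacillus-dominated, 8 with a Gardnerella-dominated and 5 with a Prevotella-dominated genital community, and the blood libraries from 4, 6 and 4 donors. Cervical libraries held 13132 to 227800 counts (median 63498) and blood libraries 14838 to 174380 (median 52004), a difference that did not pass (permutation p = 0.130, adjusted p = 0.454). Between 2611 and 8369 genes had at least 1 count in a library. The comparisons asked whether antigen presenting cells differ with the genital community, in the cervix and in blood, and between the sites.

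In the cervix, IL6, a cytokine that drives acute inflammation, was 7.66-fold higher in the 8 Gardnerella than in the 5 Lactobacillus libraries (log2 fold change 2.94 ± 0.56 SE, edgeR adjusted p = 0.0287). Its level was 674 ± 385 CPM (SD, n = 8) against 88.9 ± 67.5 CPM (SD, n = 5), and all 8 Gardnerella libraries lay above the highest Lactobacillus library. As a group, inflammatory cytokines rose (camera adjusted p = 0.0192), and 9 of 9 tested members had a positive log2 fold change (median 1.59). Of these 1 passed over all genes and 4 passed adjusted over the list alone, namely IL6, IL1B (1.59), the growth factor EREG (1.89) and OSM (1.95). Anti-inflammatory regulators also rose (adjusted p = 0.0192), with 10 of 11 members positive (median 0.97). None passed over all genes and 5 passed adjusted over the list alone. These included IL10 (2.71), a cytokine that restrains myeloid activation, and IL1RN (1.65), which blocks the IL1 receptor. NF-kB target genes rose (adjusted p = 0.0315), with 20 of 21 members positive (median 1.06). None passed over all genes and 9 passed adjusted over the list alone, such as the feedback inhibitor TNFAIP3 (1.39) and PTGS2 (1.98), the inducible enzyme of prostaglandin synthesis. NF-kB targets share 1 tested member with inflammatory cytokines and 2 with anti-inflammatory regulators, so these lists are not independent.

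IL6 was the only 1 of 857 genes past the threshold in this comparison, and 93 had an unadjusted p under 0.05, where 42.85 would be expected by chance. The genes with the next smallest p were SERPINB9, an inhibitor of granzyme B (log2 fold change 1.42 ± 0.34), THBS1, a matrix glycoprotein (2.54 ± 0.60), IL10 (2.71 ± 0.67) and EREG (1.89 ± 0.47). They were followed by MIR155HG, the host transcript of a microRNA of activated myeloid cells (2.42 ± 0.63), IL1B (1.59 ± 0.42), the transferrin receptor gene TFRC (1.59 ± 0.48), TNFAIP3 (1.39 ± 0.42) and IL1RN (1.65 ± 0.51). Adjusted p of these genes ran from 0.113 to 0.312. Panel genes had values of 1.30 for NFKBIA, 1.65 for CCL4, 0.92 for SOD2, 1.18 for CCL3 and 1.68 for TNF. Values were 2.27 ± 1.44 for CXCL10, 0.88 for IL8, 0.39 for CD83, 0.31 for LY96, -0.21 for TLR2 and -0.18 for HLA-DRA, and none of these passed. In CXCL10, 1 Gardnerella library held 11253 CPM against at most 564 CPM in the other 7, and in IL8 1 held 123940 CPM against at most 53104 CPM. The value of CXCL10 became a fall without 1 Gardnerella library (-1.02), in DESeq2 and with quality weights, and that of TLR2 a rise without 1 Lactobacillus library (0.170). Leaving out 1 library gave 0 genes in 7 of 13 cases (4 Lactobacillus and 3 Gardnerella libraries) and 2 genes in 1 case (a Gardnerella library), while DESeq2 called 7 genes, limma with quality weights 5 and a fit without the filter 3. The 3 list calls were lost when only the libraries of these communities were fitted, which called 2 genes (adjusted p = 0.0576 to 0.0581), and that of NF-kB targets also without either of 2 Lactobacillus libraries or 1 Gardnerella library (0.0941, 0.0920 and 0.0678), with a minimum count of 3 (0.0633), no filter (0.191) or all 32 libraries (0.0638), as was that of anti-inflammatory regulators with a minimum count of 3 (0.0570) or no filter (0.304).

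Cervical Prevotella libraries had more IL6 (7.77-fold, log2 fold change 2.96 ± 0.59), IL10 (9.80-fold, 3.29 ± 0.70) and MIR155HG (8.59-fold, 3.10 ± 0.67) than Lactobacillus libraries, each with an edgeR adjusted p of 0.0377. Mean levels in the 5 Prevotella and 5 Lactobacillus libraries were 701 ± 502 and 88.9 ± 67.5 CPM (SD) for IL6, 455 ± 365 and 40.4 ± 29.4 CPM for IL10, and 659 ± 420 and 72.0 ± 42.8 CPM for MIR155HG. IL6 and MIR155HG were above the highest Lactobacillus library in all 5 Prevotella libraries, and IL10 in 4 of 5. NF-kB target genes rose as a group (camera adjusted p = 0.0192), with 20 of 21 members positive (median 1.49). None passed over all genes and 13 passed adjusted over the list alone, among them the adhesion molecule ICAM1 (1.54), the survival gene BCL2A1 (2.04) and TNF (2.49). Inflammatory cytokines rose (adjusted p = 0.0192), with 9 of 9 members positive (median 1.98). Of these 1 passed over all genes and 6 adjusted over the list alone, which were IL6, IL1B (1.98), OSM (2.33), IL1A (2.35), EREG (1.35) and TNF. Anti-inflammatory regulators rose (adjusted p = 0.0245), with 9 of 11 members positive (median 0.72), 1 past over all genes and 4 adjusted over the list alone. The 5 Lactobacillus libraries were those of the Gardnerella comparison, so both share their chance values and no overlap between them is given.

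**Figure D1:**
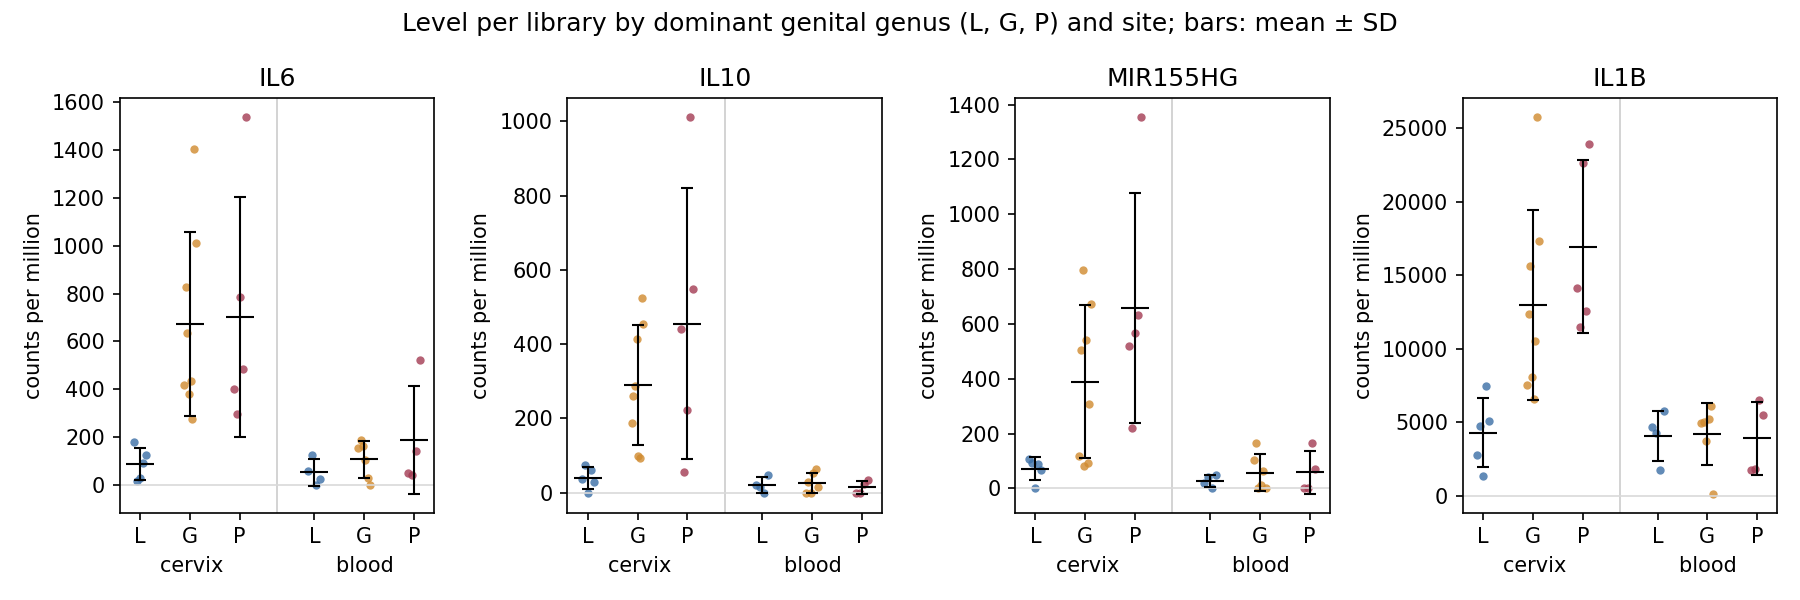
Level of IL6, IL10, MIR155HG and IL1B in CPM (vertical axes, linear) in each library, by the dominant genus (L, Lactobacillus; G, Gardnerella; P, Prevotella) in cervix and blood; each point is a library, and bars are mean ± SD. Cervical IL6 ran from 277 to 1403 CPM in the 8 Gardnerella and from 297 to 1538 CPM in the 5 Prevotella libraries, above the highest of the 5 Lactobacillus libraries at 181 CPM.

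These 3 genes were the only ones of 857 past the threshold, and 102 had an unadjusted p under 0.05. The genes with the next smallest p were IL1B (1.98 ± 0.45, adjusted p = 0.0560), ICAM1 (1.54 ± 0.38) and the ribosomal protein gene RPLP2 (-3.04 ± 0.75, both 0.0790). They were followed by PDE4B, a phosphodiesterase that degrades cyclic AMP (1.68 ± 0.45), the chemokine CCL4 (2.37 ± 0.64), the mitochondrial superoxide dismutase SOD2 (1.47 ± 0.40) and BCL2A1 (2.04 ± 0.55), each with an edgeR adjusted p of 0.0980. Mean IL1B was 16947 ± 5871 CPM in Prevotella, 12972 ± 6446 CPM in Gardnerella and 4277 ± 2337 CPM in Lactobacillus libraries (SD, n = 5, 8 and 5). The remaining panel genes had log2 fold changes of 1.84 for IL1RN, 1.45 for NFKBIA, 2.49 for TNF, 2.03 for IL8 and 1.04 for LY96. Values were 1.27 for CCL3, 0.68 for CD83, 0.55 for HLA-DRA, 1.46 for CXCL10 and 0.32 for TLR2. In TNF, 1 Prevotella library held 1825 CPM against at most 472 CPM in the other 4. The log2 fold change of TNF ran from 1.63 to 3.18 over the alternatives. The count fell to 0 without any 1 of the 5 Lactobacillus or of 4 of the Prevotella libraries and reached 11 without the other Prevotella library; it was 42 with DESeq2, 20 without the filter, 6 with all 32 libraries, 5 without the cervical library under 30000 counts, 1 with quality weights and 0 with only these 2 communities. That last fit also ended the 3 list calls (adjusted p = 0.0652, 0.0687 and 0.111), leaving out 1 Prevotella library ended those of NF-kB targets and anti-inflammatory regulators (both 0.0611), and the latter also missed with quality weights (0.0740), a minimum count of 3 (0.0591) or no filter (0.0509).

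**Figure D2:**
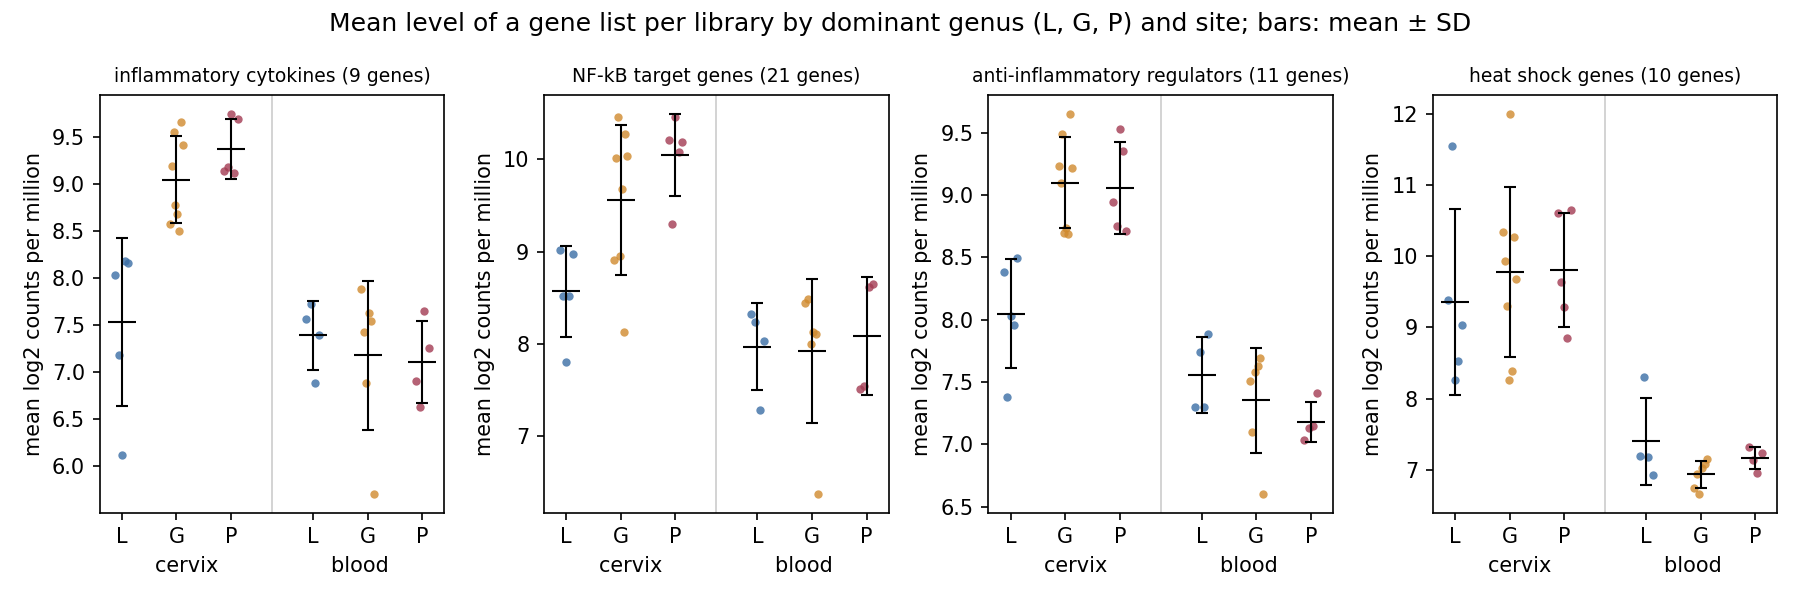
Mean log2 CPM of the tested members of 4 gene lists in each library (vertical axes), by the dominant genus (L, G, P) in cervix and blood; points are libraries, and bars are mean ± SD. All 8 Gardnerella and all 5 Prevotella cervical libraries lie above the highest Lactobacillus library for inflammatory cytokines and anti-inflammatory regulators, as do 5 of 8 and 5 of 5 for NF-kB target genes, while heat shock genes overlap between communities and lie higher in the cervix than in blood.

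Several other immune lists in the cervix had positive medians without passing. Chemokines had medians of 1.18 (Gardnerella against Lactobacillus) and 1.46 (Prevotella against Lactobacillus) over 11 members, with camera adjusted p = 0.143 and 0.178. Adjusted over the list alone, 0 and 1 members passed, the latter CCL4. Type I interferon-stimulated genes had medians of 1.96 and 1.30 over 6 members (adjusted p = 0.286 and 0.401), with IFIT2 (3.09) and EPSTI1 (2.01) past in the first adjusted over the list alone. In IFIT2, 1 Gardnerella library held 5617 CPM against a group mean of 1049 CPM. Dendritic cell maturation genes had medians of 0.85 and 1.13 over 8 members (0.161 and 0.0892), with 2 members past in each adjusted over the list alone, in Prevotella ICAM1 and BIRC3. Both ICAM1 and BIRC3 are also on the NF-kB target list. Inflammasome genes had medians of 0.66 and 0.47 over 6 members (0.143 and 0.364), with 1 past in each adjusted over the list alone. Immediate early genes had medians of 0.65 and 0.76 over 11 members (0.194 and 0.178), with 0 past. With the preset correlation these 5 lists passed in both comparisons (adjusted p from 0.000994 to 0.0286), except inflammasome genes in Prevotella (0.0574). With an estimated correlation none of these calls held in the reported fit. In Prevotella, chemokines, dendritic cell maturation and inflammasome genes passed without the filter. Chemokines there also passed without 1 Lactobacillus library and maturation genes without 1 Prevotella library or with fry, which does not compare a list with other genes. Immediate early genes passed in both comparisons without 1 Lactobacillus library. Genes of MHC class II presentation had medians of -0.42 and -0.25 over 14 members (0.878 and 0.927) and those of MHC class I 0.38 and 0.24 over 10 (0.878 and 0.839). Heat shock genes had medians of 0.13 and 0.04 over 10 members, glycolysis and hypoxia genes -0.16 and -0.22 over 10, and lipid handling genes -0.10 and -0.02 over 8. Oxidative stress and metal genes had medians of 0.01 and -0.22 over 10 members, with 1 higher and 1 lower in Prevotella adjusted over the list alone. Matrix remodelling genes had medians of 0.35 and -0.07 over 9 members, with 2 past in each adjusted over the list alone, and classical monocyte markers 0.23 and 0.43 over 8. These 6 lists had adjusted p from 0.454 to 0.987. Mean and median differed in sign for oxidative stress genes (mean -0.06) and glycolysis genes (0.06) in Gardnerella, and for matrix (0.48) and heat shock genes (-0.04) in Prevotella. The other 14 lists had fewer than 5 tested members in the cervix, and 0 of these members passed.

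Markers of other cells were measured in the same libraries. Tested neutrophil markers had medians of 1.11 (Gardnerella) and 1.60 (Prevotella) over 5 members, all positive, with adjusted p of 0.795 and 0.401 with an estimated correlation, and 0.0494 for Prevotella with the preset one. HCAR3 (3.03) and G0S2 (1.60) passed in Prevotella adjusted over the list alone. G0S2 is also on the NF-kB target list. The summed level of all neutrophil markers was 3751 ± 2242 CPM in Prevotella and 1735 ± 697 CPM in Lactobacillus libraries (n = 5 each, exact permutation p = 0.0873, adjusted p = 0.306). Macrophage markers summed to 817 ± 355 CPM in Prevotella, 959 ± 447 CPM in Gardnerella and 1646 ± 897 CPM in Lactobacillus libraries (exact permutation p = 0.0317 and 0.0707 against Lactobacillus, adjusted p = 0.222 and 0.341). Langerhans cell markers summed to 91.6 ± 54.8 CPM in Prevotella, 66.8 ± 47.5 CPM in Gardnerella and 225 ± 205 CPM in Lactobacillus libraries (exact permutation p = 0.270 and 0.0730 against Lactobacillus, adjusted p = 0.444 and 0.341). Plasmacytoid dendritic cell markers summed to 142 ± 44.0 CPM in Gardnerella and 246 ± 87.3 CPM in Lactobacillus libraries (n = 8 and 5, exact permutation p = 0.00622, adjusted p = 0.0870). NK and cytotoxic markers summed to 107 ± 65.4 CPM in Prevotella and 317 ± 185 CPM in Lactobacillus libraries (exact permutation p = 0.0317, adjusted p = 0.222). B and plasma cell markers summed to 8.18 ± 7.94 CPM in Prevotella, 94.1 ± 93.0 CPM in Gardnerella and 112 ± 106 CPM in Lactobacillus libraries (Prevotella against Gardnerella exact permutation p = 0.0109, adjusted p = 0.152; against Lactobacillus 0.0556 and 0.259). The share of ribosomal protein transcripts was 13.9% ± 1.75 in Lactobacillus, 10.5% ± 3.45 in Gardnerella and 8.44% ± 4.03 in Prevotella libraries (n = 5, 8 and 5; Prevotella against Lactobacillus exact permutation p = 0.0238, adjusted p = 0.0833).

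Between Prevotella and Gardnerella cervical libraries no gene passed. IL6 had a log2 fold change of 0.02 ± 0.46, IL1B 0.39 ± 0.39, TNF 0.80 ± 0.75 and IL8 1.15 ± 0.73. The smallest unadjusted p belonged to PDE4B (1.01 ± 0.39), MT1X, a metallothionein (-2.68 ± 1.06), HCAR3, a receptor for hydroxylated fatty acids (1.92 ± 0.79), RPS14 (-1.40 ± 0.61) and TXNIP (-1.32 ± 0.62). They were followed by IL1A (1.35 ± 0.66), IFI16 (0.91 ± 0.45), LAMTOR3 (0.85 ± 0.42), OFD1 (-0.77 ± 0.39) and HLA-DRA (0.73 ± 0.37). For CXCL10 the value was -0.80 and for LY96 0.73. The sign for CXCL10 turned without 1 Gardnerella library (2.51), in DESeq2 (2.42) and with quality weights (1.10), that for TNF without 1 Prevotella library (-0.113), and that for IL6 in 9 of 23 settings. With edgeR 0 of 857 genes passed and 5 had an unadjusted p under 0.05, and DESeq2 and limma with quality weights also called 0. No list passed with an estimated correlation (lowest adjusted p = 0.653). With the preset one NF-kB targets (0.000567, median 0.30) and neutrophil markers (0.0382, median 0.44) did. Of the panel, 4 genes were too low to test in the cervix. Their mean levels in Lactobacillus, Gardnerella and Prevotella libraries were 130, 119 and 144 CPM for CCL5, 45.1, 126 and 110 CPM for TLR4, 207, 107 and 64.8 CPM for CD14, and 83.0, 399 and 163 CPM for ISG15. Single libraries weigh on these means: 1 Gardnerella library held 2335 CPM of ISG15 (others at most 370), 1 held 419 CPM of CD14 (at most 119) and 1 held 404 CPM of TLR4 (at most 127), and 1 Lactobacillus library held 585 CPM of CD14 (at most 154).

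In blood cells no gene passed between the communities with edgeR. Of the panel, IL6, TNF, IL1RN, CXCL10, ISG15, CCL5, TLR4 and CD14 were too low to test there. The inflammatory cytokine list had fewer than 5 tested members, so a community difference in these genes is not excluded in blood. Mean IL6 was 53.0 ± 55.2, 107 ± 76.0 and 190 ± 226 CPM in Lactobacillus, Gardnerella and Prevotella libraries. Mean IL1B was 4084 ± 1707, 4185 ± 2131 and 3897 ± 2478 CPM in Lactobacillus, Gardnerella and Prevotella libraries (SD, n = 4, 6 and 4), and IL8 9358 ± 4459, 9256 ± 5298 and 9579 ± 5765 CPM. The smallest p in Prevotella against Lactobacillus went to lower values for the MHC class II gene HLA-DPB1 (-2.02 ± 0.46), HLA-DRB1 (-1.86 ± 0.48), CSF1R, the receptor of the macrophage growth factor CSF1 (-2.28 ± 0.57), RFC1 (-2.21 ± 0.48), CTBP2 (-2.78 ± 0.65), NIPBL (-2.16 ± 0.51) and RPLP0 (-1.26 ± 0.33). Higher values were found for PSAP, the precursor of the saposins (1.39 ± 0.32), the catalase gene CAT (1.67 ± 0.42) and CARD16 (1.18 ± 0.30). The edgeR adjusted p of each of these genes was 0.0619. Gardnerella against Lactobacillus gave its smallest p to HLA-DRB1 (-1.49 ± 0.41), CD164 (1.19 ± 0.33), PPT1 (1.10 ± 0.32), RAB12 (1.23 ± 0.38) and CAT (1.24 ± 0.39). They were followed by HLA-DPB1 (-1.18 ± 0.39), ARPC1B (-1.47 ± 0.51), CARD16 (0.78 ± 0.28), SERPINA1 (1.30 ± 0.48) and RFC1 (-1.04 ± 0.39), with adjusted p from 0.685 to 0.900. For Prevotella against Gardnerella these were RPL22 (-0.65), RPS23 (0.92), HINT1 (-0.94), C3AR1 (1.80), RPL5 (-0.70), RPS25 (-0.81), GPX1 (-1.19), RPL30 (-0.64), POMP (0.76) and ARID5B (1.48), all at 0.522. HLA genes are polymorphic and ribosomal protein genes have many processed copies, so their counts are uncertain where the alignment could not place a read. The log2 ratio of RPS23 to RPL24 ranged over 4.73 within the blood Gardnerella libraries.

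With edgeR no gene of 746 passed in blood: 0 in Gardnerella against Lactobacillus, with 38 at an unadjusted p under 0.05, 0 in Prevotella against Lactobacillus, with 131, and 0 in Prevotella against Gardnerella, with 65. DESeq2 called 0, 18 (5 higher, 13 lower) and 0 genes, and limma with quality weights 0 in each. Prevotella against Lactobacillus also gave 5 genes with a minimum count of 3, 8 without the filter, 7 with only these 2 communities and 3 with all 32 libraries, and 2 and 16 without either of 2 Prevotella libraries, while Prevotella against Gardnerella gave 1 gene without the filter and 1 without 1 Gardnerella library. Genes of MHC class II presentation had a median of -0.64 in Prevotella against Lactobacillus, with 10 of 11 members negative and 2 lower adjusted over the list alone (camera adjusted p = 0.449). Without the filter this list passed. In Gardnerella against Lactobacillus the median was -0.27, with 9 of 11 negative and 2 lower adjusted over the list alone (0.451). The 9 other lists with 5 or more tested members in blood (NF-kB targets, MHC class I, inflammasome genes, anti-inflammatory regulators, oxidative stress, glycolysis, matrix remodelling, immediate early genes and classical monocyte markers) had adjusted p from 0.451 to 0.997 in the 3 comparisons. Of their members, 1 inflammasome gene was higher, and 1 anti-inflammatory regulator and 1 immediate early gene lower, in Prevotella against Lactobacillus adjusted over the list alone.

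Whether a community difference itself differed between the sites was tested directly. For inflammatory cytokines the Gardnerella-Lactobacillus difference was larger in the cervix than in blood by a median of 1.92 on the log2 scale, with 10 of 10 members positive (camera adjusted p = 0.0163), and the Prevotella-Lactobacillus difference by a median of 2.17, again with 10 of 10 members positive (0.0265). For anti-inflammatory regulators these medians were 1.06 (10 of 12 positive, adjusted p = 0.0196) and 1.44 (11 of 12 positive, 0.0265). Several members had few counts in a blood community, among them OSM (0 in Prevotella), VEGFA (5 in Prevotella), IL6 (13 in Lactobacillus) and IL10 (3 in Prevotella). The size of these medians is therefore uncertain. Over all genes no member of either list passed. Adjusted over the list alone, 0 and 0 members passed in Gardnerella and 1 and 3 in Prevotella. The other 16 lists did not pass (lowest adjusted p = 0.130 and 0.200), but immediate early genes passed in both terms without 1 cervical Lactobacillus library. All 4 list calls were lost over the 12 donors with paired libraries, both with a replicate block (adjusted p = 0.490 for each Gardnerella list, 0.420 for cytokines and 0.741 for regulators in Prevotella) and without one (0.541, 0.541, 0.630 and 0.910). Most of these 12 donors had a Gardnerella or Prevotella community. Few Lactobacillus donors were left as the reference, so a smaller group alone could end the calls. Quality weights also ended all 4 (0.0538, 0.0980, 0.0522 and 0.0792), and no filter ended 3, all but cytokines in Prevotella. A minimum count of 3 and leaving out libraries under 30000 counts each ended both calls of regulators, and median ratio scaling that in Prevotella. Leaving out 1 library ended the call of regulators in Gardnerella for 2 blood Lactobacillus (0.0519 and 0.101) and 1 blood Gardnerella library (0.0546), and in Prevotella that of both lists for 1 cervical Lactobacillus (0.0593 for both), 2 blood Lactobacillus (0.0553 and 0.0506 for cytokines, 0.0553 and 0.0923 for regulators) and 2 blood Prevotella libraries (0.0913 and 0.0519, 0.0913 and 0.206), and that of regulators for 1 more blood Lactobacillus library (0.0531).

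No single gene passed these terms in edgeR: 0 of 1135 for Gardnerella, with 63 at an unadjusted p under 0.05 and a smallest adjusted p of 0.849, and 0 for Prevotella, with 110 and 0.173. DESeq2 and limma with quality weights called 0 in both. The Prevotella term gave 3 genes without the filter and 4 without 1 blood Prevotella library. The smallest p in the Gardnerella term belonged to CD164 (-1.67 ± 0.46), THBS1 (2.98 ± 0.92), RAB12 (-1.64 ± 0.53), CCR7, a receptor of migrating dendritic cells, and IFIT3 (3.58 ± 1.18). They were followed by NDUFA7 (-2.89 ± 0.97), CREM (2.34 ± 0.80), SAT1 (1.27 ± 0.46), INHBA and IFIT2 (3.86 ± 1.45). INHBA had 0 counts and CCR7 2 counts in the 6 blood Gardnerella libraries, so no value is given for them. In the Prevotella term it belonged to the transcription factor ETS2 (4.07 ± 0.97), NIPBL (2.64 ± 0.66), SAT1 (1.98 ± 0.51) and OSM. Next were G0S2 (2.90 ± 0.80), RPS9 (-3.46 ± 0.96), RPL24 (2.14 ± 0.64), PDE4B (2.34 ± 0.73), CTBP2 (2.40 ± 0.77) and PLAUR (2.08 ± 0.67). OSM had 0 counts in the 4 blood Prevotella libraries, so no fold is given.

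Cervical and blood cells differed in 593 of 1135 genes (363 higher and 230 lower in the cervix, edgeR, n = 18 and 14). SPP1, which encodes the matrix protein osteopontin, was higher, with 11483 ± 11290 CPM in the cervix and 272 ± 782 CPM in blood. Its size is uncertain: the fit, which averages the communities on the log scale, gave a log2 fold change of 7.05 ± 0.88 (8.27 without 1 blood Lactobacillus library), and the ratio of pooled counts was 32.9. In blood 7 of 14 libraries had a count of SPP1 and 1 held 2940 CPM. The inducible heat shock gene HSPA1A (6.66 ± 0.95) and its partner DNAJB1 (5.52 ± 0.81) also rose, from 8 and 6 counts in blood (ratios of pooled counts 81.3, exact 95% counting interval 41.1 to 189, and 52.7, interval 24.0 to 144). The macrophage elastase MMP12 rose as well, from 10 counts in 2 blood libraries with 0 in a community (ratio of pooled counts 41.3, interval 22.3 to 86.6). By the fitted value, the 6 largest rises also included the epithelial genes SPRR3 and PI3, an order that other measures change. SPRR3 had 299 counts in the cervix and 0 in blood and was at least 61.3-fold higher against a floor of 3 counts over the blood group. PI3 had 390 and 2 counts (ratio of pooled counts 119.9, exact 95% counting interval 32.97 to 993.5). The largest falls were in IGJ, the joining chain of secreted antibodies (-3.08 ± 0.62), LGALS2 (-2.54 ± 0.37), MGST1 (-2.50 ± 0.34), FCER1A, a receptor subunit of blood dendritic cells (-2.37 ± 0.42), the scavenger receptor CD36 (-1.96 ± 0.28) and CALM2 (-1.92 ± 0.21).

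Members of the immune lists are given here as single genes, since no list passed the camera test with an estimated correlation between the sites in the reported fit. Over all 1135 tested genes 363 rose and 230 fell, so tallies near these shares, here and below, tell little about a list. Of 13 tested chemokines, 11 rose over all genes and adjusted over the list alone (median 2.84). The smallest p went to the neutrophil attractants CXCL1 (3.80 ± 0.48) and CXCL5 (ratio of pooled counts 31.5, interval 13.3 to 97.8, with 5 counts in blood). By the ratio of pooled counts CCL8 was larger than either (85.3, interval 29.0 to 415, with 3 counts in blood). Inflammatory cytokines rose in 8 of 10 (VEGFA 2.64; OSM, ratio of pooled counts 10.9, interval 7.25 to 17.3), and adjusted over the list alone 8 rose and 1 fell. NF-kB targets rose in 18 of 21 (SOD2 2.60, PLAUR 2.17; list alone, 20), and dendritic cell maturation genes in 7 of 8 in both counts (ICAM1 2.43, IDO1 3.93). Anti-inflammatory regulators rose in 8 of 12 (IL1RN 3.35, IL10 3.20; list alone, 10). Immediate early genes rose in 11 of 12 in both counts (NR4A3 2.10, EGR1 2.90), and LPS and Toll-like receptor genes in 3 of 6 in both counts (TLR2 1.23, NFKB1 1.51). Of 6 inflammasome genes, IL1B rose (1.54) and CARD16 (-0.70), NLRP3 (-1.08) and CASP1 (-0.51) fell, in both counts. Of 10 interferon-stimulated genes 5 rose, among them IFIT3 (1.94) and RSAD2 (3.29, with 1 cervical library at 5290 CPM against a mean of 459 CPM), and 2 fell, OAS1 (-1.39) and TRIM22 (-0.90); adjusted over the list alone 6 rose and 2 fell.

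**Figure D3:**
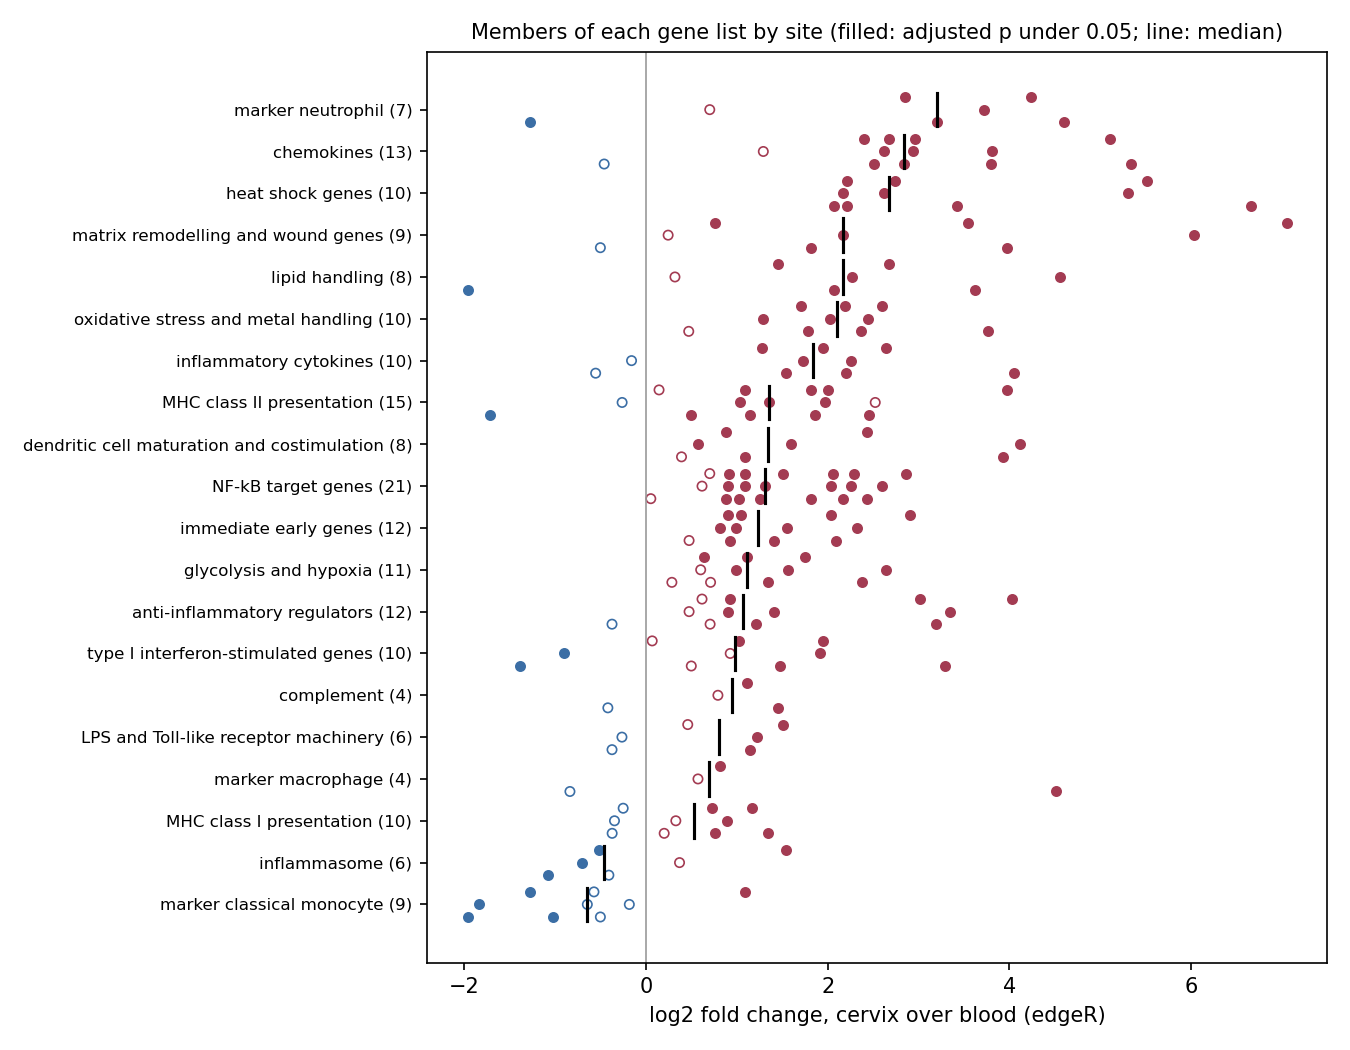
Log2 fold change of cervix over blood (horizontal axis, edgeR) for each tested member of the fixed gene lists with 4 or more tested members, list sizes in parentheses; filled points passed an adjusted p of 0.05 over all genes, open points did not, and black lines are list medians. All 10 heat shock genes lie above 0 (median 2.68), and 8 of 9 classical monocyte markers lie below 0 (median -0.65).

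All 10 heat shock genes rose in both counts (median 2.68; HSP90AA1 3.42, HSP90AB1 2.17), and collection of the cells also differed between the sites. Among metabolic lists, 9 of 10 oxidative stress and metal genes rose (FTH1 2.02, SOD2 2.60; list alone, 10). Of 11 glycolysis and hypoxia genes 8 rose (the glucose transporter SLC2A3 2.38, LDHA 1.75; list alone, 10). Of 8 lipid handling genes 6 rose (APOC1 4.56, with 5 counts in blood, and OLR1 3.62) and CD36 fell, in both counts. Matrix remodelling genes rose in 7 of 9 in both counts (TIMP1 3.54, CTSL 3.97). In MHC class II presentation 11 of 15 genes rose and 1 fell (list alone, 12 and 1), with CTSB at 2.45, HLA-DRA at 1.08 and CTSS at -1.72. In MHC class I presentation 5 of 10 rose in both counts (HLA-B 0.76). Complement genes rose in 2 of 4 in both counts (ITGAX 1.45, C3AR1 1.11).

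Cell type markers moved in both directions. Among 9 classical monocyte markers 4 fell, including LYZ (-1.84) and CD36, and CLEC4E rose (1.09), in both counts. The sum of this list was 12643 ± 4611 CPM in the cervix against 38831 ± 11575 CPM in blood (permutation adjusted p = 5.6e-05). Conventional dendritic cell markers fell in 2 of 2 (FCER1A, CPVL -1.33; sum 530 ± 302 against 1475 ± 380 CPM, 5.6e-05). This sum was mostly CPVL, which alone was at 446 ± 242 against 1193 ± 392 CPM on the scale of the fit. Macrophage markers rose in 2 of 4 (GPNMB 4.51, with 6 counts in blood, and CD163 0.82; list alone, 2 rose and 1 fell; sum 1110 ± 649 against 655 ± 231 CPM, 0.0275). Nonclassical monocyte markers split into FCGR3A (-1.41) and IFITM2 (1.11), with a sum that did not pass (adjusted p = 0.571). Of 7 neutrophil markers 5 rose, among them FCGR3B (ratio of pooled counts 22.2, interval 10.1 to 61.3, with 6 counts in blood) and HCAR3 (2.85), and S100A12, which monocytes also express, fell (-1.28; list alone, 6 and 1). Their sum of 2752 ± 1744 against 2402 ± 720 CPM did not pass (0.999). It was weighted to S100A12 (895 counts in the cervix and 1360 in blood) and G0S2 (1902 and 599). These are also on the classical monocyte and NF-kB target lists. HCAR3 had 504 and 30 counts and FCGR3B 217 and 6, so the sum can mask rises of single markers. FCGR3B is a near copy of FCGR3A and the split of their reads is uncertain. Epithelial markers rose in 2 of 2 (sum 661 ± 689 against 33.8 ± 19.9 CPM, 5.6e-05), with a fitted median of 6.46 that became 6.04 with SPRR3 at its bound. IL7R, the T cell marker tested, rose (3.05; sum 598 ± 480 against 308 ± 354 CPM, 0.0308). IL7R alone had 601 counts in the cervix and 51 in blood (ratio of pooled counts 7.25, interval 5.44 to 9.84). The higher T cell sum may therefore be that of IL7R alone, and a sum without IL7R was not tested. Sums were also higher for plasmacytoid dendritic cells (173 ± 86.5 against 52.4 ± 28.5 CPM, 5.6e-05) and Langerhans cells (118 ± 128 against 20.1 ± 18.9 CPM, 0.000537). The Langerhans list shares EPCAM and CDH1 with the epithelial list, so these sums are not independent. The sum was lower for B and plasma cells (75.2 ± 90.1 against 238 ± 250 CPM, permutation adjusted p = 0.0332), with a fall in IGJ. The stroma and endothelium sum was also lower (154 ± 75.7 against 488 ± 200 CPM, permutation adjusted p = 5.6e-05). It was mostly PECAM1 (-1.40), which alone was at 197 ± 86.4 against 524 ± 204 CPM on the scale of the fit. For erythroid cells and platelets the log2 sum was lower in the cervix (difference -1.22, adjusted p = 0.0308) although the mean was higher (447 ± 1136 against 387 ± 154 CPM), and 0 of 2 members passed. Among genes named for the sites, CD163 passed in 30 of 43 settings, IFITM2 in 38, RSAD2 and C3AR1 in 39, CARD16 and HLA-B in 41 and PI3 in 42. Leaving out 1 blood Lactobacillus library, the same for each, raised the fitted values of SPP1 (8.27), HSPA1A (7.93), GPNMB (5.34), OLR1 (4.22) and IL7R (3.95), and those of APOC1 and MMP12. NK (0.881) and mast cell sums (0.0903) did not pass, and none of their members was tested.

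In the reported fit no list passed the camera test between the sites with an estimated correlation (lowest adjusted p = 0.142), against 13 of 18 with the preset one. With the estimated one, 2 of 24 lists passed at a minimum count of 3 (chemokines and matrix remodelling genes) and 14 of 30 without the filter, among them NF-kB targets, cytokines and heat shock genes. With fry 15 of 18 passed. The median log2 fold change of all genes was 0.11 with TMM, 0.21 with median ratio factors, -0.06 with upper quartile scaling and -0.11 without scaling. The share of calls that were higher in the cervix was 61.2%, 65.4%, 46.7% (293 higher, 335 lower) and 45.6% in that order, and DESeq2 called 1240 genes, a minimum count of 3 gave 1201 and no filter 1284. Ribosomal protein transcripts made up 10.9% ± 3.74 of cervical and 19.03% ± 2.754 of blood counts (permutation p = 1e-05, the smallest possible, adjusted p = 7e-05). MALAT1, a nuclear RNA, made up 15.8% ± 5.31 and 10.4% ± 1.89 (0.00525), and IL8 3.82% ± 3.37 and 0.754% ± 0.372 (0.0049).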

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

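The tests of the RPS23 and RPL24 ratio, of the heat shock genes and of counts at an unadjusted p were chosen after the results were seen.

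Among 90 tests of library measures and of single panel genes within a group, 10 had 1 library far from the rest, all in panel genes of cervical libraries. Over all 90, chance would give about 4.5 for values that follow a normal distribution, which CPM values need not. These libraries held 1825 CPM of TNF in cervical Prevotella (others at most 472), 123940 CPM of IL8 in Gardnerella (at most 53104) and 1372 CPM of CXCL10 in Lactobacillus (at most 198). In cervical Gardnerella, 1 library each held 11253 CPM of CXCL10 (others at most 564), 1019 CPM of TLR2 (at most 428), 404 CPM of TLR4 (at most 127), 419 CPM of CD14 (at most 119) and 2335 CPM of ISG15 (at most 370). In cervical Lactobacillus, 1 library held 585 CPM of CD14 (others at most 154) and 1 held 318 CPM of LY96 (others at least 527). Symbols turned into dates, which no comparison used, held 0.132% of counts.

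The community differences of inflammatory cytokines and anti-inflammatory regulators were larger in the cervix than in blood, by a test of the difference itself (camera adjusted p = 0.0163 and 0.0196 for Gardnerella, 0.0265 and 0.0265 for Prevotella). Several members had few counts in a blood community, so the size of these differences is uncertain. Of 100 splits of the donors, the real one included, 1, 1, 1 and 4 gave a camera value as large in that order. Only lists that had passed camera were split, and the splits do not allow for that choice, so chance is not excluded. All 4 calls were also lost over the 12 donors with both sites, with a replicate block (camera adjusted p = 0.490, 0.490, 0.420 and 0.741) and without it, and 3 of them without single libraries. Few of these 12 donors had a Lactobacillus community, so their loss cannot be told apart from that of a smaller reference group. The real values were 3.04, 2.66, 2.63 and 2.53 and the highest others 2.47, 2.65, 2.34 and 3.07. A count of 0 genes says nothing about chance, since all 100 splits reach it (highest others 2 and 4). Of the genes at an unadjusted p under 0.05 in edgeR, 16 of 100 splits gave as many in the Gardnerella term (63, highest other 90). In the Prevotella term 3 did (110, highest other 144), but this measure was chosen after the results, so chance is not excluded in either term. DESeq2 and limma with quality weights called 0 genes in both.

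NF-kB target and cytokine genes were higher in cervical Prevotella than in Lactobacillus libraries (28 of 29 members, median 1.49). After thinning 17 libraries to 32708 counts the median was 1.54 against 1.51 before (95% interval 1.34 to 1.70 by resampling the member genes, which takes them as independent). Random thinning keeps the expected share of each gene, so this median could hardly fall. The thinning therefore cannot decide on depth as a cause. For RNA of neutrophils, which the gate on HLA-DR should remove, the sum of 23 markers was a covariate (log2 difference 1.08, exact permutation p = 0.286). The median was then 1.37 (interval 0.960 to 1.52), which argues against neutrophil RNA only as far as this sum tracks it. With 10 heat shock genes as a covariate the median was 1.58 (interval 1.31 to 1.73). This cannot decide on handling stress, since the heat shock level hardly differed between the groups (log2 difference 0.403, exact permutation p = 0.579). A response of the cells to the community may explain the pattern, and so may a different mix of sorted cells, which the marker sums leave open (macrophage markers 817 against 1646 CPM, exact permutation adjusted p = 0.222). Of 100 splits, the real one included, 1 gave as many genes (3, highest other 1). For NF-kB targets (2.65, highest other 2.19) and cytokines (2.83 and 2.71) 1 split each gave as large a value. For anti-inflammatory regulators (2.36 and 2.92) 2 did. Splits rarely reached these values. Chance is not excluded by this, since only lists that had passed were split and 9 of 10 fits without 1 library gave 0 genes.

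In blood Prevotella against Lactobacillus, 26 of 68 tested ribosomal protein genes had an unadjusted p under 0.05, of which RPS23 (1.17) and RPS9 (2.56, with 1 of 4 Prevotella libraries at 7217 CPM) were higher and 24 lower, among them RPL24 (-2.34). The log2 ratio of RPS23 to RPL24 was 3.75 ± 1.74 in Prevotella, 1.31 ± 1.71 in Gardnerella and 0.05 ± 0.33 in Lactobacillus libraries (SD, n = 4, 6 and 4). Without the most extreme Prevotella library the difference of 3.70 became 2.94. This does not decide on 1 library as the cause, since both genes were chosen for the pattern and the exact permutation p lay at its smallest possible value (0.0286) both times. The ratio ranged over 4.73 within the Gardnerella libraries, more than the difference between the communities. This is consistent with a structure of the libraries other than the community, such as a batch that the labels do not give, or reads shared with processed copies, which was not tested.

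All 10 heat shock genes were higher in the cervix than in blood (median 2.68). The tables argue against the scaling as the cause, since the lowest median over 4 scalings was 2.32. In 16 of 18 cervical libraries the mean heat shock level lay above that of the highest blood library. Collection and sorting differed with the site, so a response of cells in the tissue and a response to collection cannot be told apart, because the site and the collection coincide in all libraries.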

How the results depend on the processing

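The fit without libraries under 30000 counts was chosen after the data were seen, and the other alternatives were planned. No called result changed sign, and no cause of a change was tested beyond what the settings themselves do, such as fewer libraries or more genes tested.

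Cervical Gardnerella against Lactobacillus (1 gene) gave 7 genes with DESeq2, 5 with limma with quality weights, 3 without the filter, 2 with only these communities and 0 to 2 without 1 library. The adjusted p of NF-kB targets was 0.0633 with a minimum count of 3, 0.191 without the filter, 0.0581 with only these communities, 0.0638 with all 32 libraries and 0.0212 to 0.0941 without 1 library. That of cytokines was 0.0576 with only these communities and 0.00811 to 0.0426 without 1 library, and that of anti-inflammatory regulators was 0.0570, 0.304 and 0.0576 with a minimum count of 3, no filter and only these communities, and 0.00457 to 0.0426 without 1 library.

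Cervical Prevotella against Lactobacillus (3 genes) gave 42 genes with DESeq2 (38 higher, 4 lower), 1 with quality weights, 20 without the filter, 5 without libraries under 30000 counts, 0 with only these communities, 6 with all 32 libraries and 0 to 11 without 1 library. With only these communities the adjusted p was 0.0652 for NF-kB targets, 0.0687 for cytokines and 0.111 for anti-inflammatory regulators. The latter had 0.0740 with quality weights, 0.0591 with a minimum count of 3 and 0.0509 without the filter. Without 1 library these ran from 0.0113 to 0.0611, 0.00647 to 0.0461 and 0.0113 to 0.0611. Without the filter chemokines, dendritic cell maturation and inflammasome genes also passed, and single libraries left out let chemokines, maturation genes or immediate early genes pass. IL6, IL10 and MIR155HG kept their sign in each setting and passed in 9 of 20, 9 of 19 and 9 of 20.

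Values of genes that did not pass changed sign in places: CXCL10 ran from -1.02 to 3.78 in Gardnerella against Lactobacillus and from -1.83 to 2.51 in Prevotella against Gardnerella, each with 3 changes of sign in 23 settings. In the latter IL6 (9 settings), CCL3 (3), TNF, IL1RN and NFKBIA (1 each) also turned, as did TLR2 (1) in the former.

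Cervical Prevotella against Gardnerella and blood Gardnerella against Lactobacillus gave 0 to 0 without 1 library. Blood Prevotella against Lactobacillus (0) gave 18 with DESeq2, 5 with a minimum count of 3, 8 without the filter, 7 with only these communities, 3 with all 32 libraries and 0 to 16 without 1 library. Blood Prevotella against Gardnerella (0) gave 1 without the filter and 0 to 1 without 1 library. Cervix against blood (593) gave 1240 with DESeq2, 1201 with a minimum count of 3, 1284 without the filter and 574 to 662 without 1 library. Of the genes named there, CD163 passed in 30 of 43 settings (adjusted p up to 0.138), IFITM2 in 38 (0.299), RSAD2 in 39 (0.234) and C3AR1 in 39 (0.102). Of its lists (0 of 18), 2 of 24 passed with a minimum count of 3 and 14 of 30 without the filter, and in blood Prevotella against Lactobacillus MHC class II presentation passed without the filter.

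Of the site by community terms, Gardnerella gave 0 to 0 genes without 1 library and Prevotella 3 without the filter and 0 to 4 without 1 library. For Gardnerella, cytokines had an adjusted p of 0.0538 with quality weights, 0.128 without the filter and 0.00462 to 0.0422 without 1 library. Anti-inflammatory regulators had 0.0980 with quality weights, 0.164 with a minimum count of 3, 0.589 without the filter, 0.0706 without libraries under 30000 counts and 0.00462 to 0.101 without 1 library. Immediate early genes passed in both terms without 1 cervical Lactobacillus library. For Prevotella, cytokines had 0.0522 with quality weights and 0.00980 to 0.0913 without 1 library. Regulators had 0.0521 with median ratio scaling, 0.0792 with quality weights, 0.190 with a minimum count of 3, 0.113 without the filter, 0.0834 without libraries under 30000 counts and 0.00980 to 0.206 without 1 library. The paired fit with a replicate block over 12 donors gave 0.490 and 0.490 (Gardnerella) and 0.420 and 0.741 (Prevotella) for cytokines and regulators, and these donors without the block 0.541, 0.541, 0.630 and 0.910. The calls were thus lost with these donors whether or not the block was used. Few of these donors had a Lactobacillus community, so a smaller group alone could end the calls. Between the sites the block gave 502 genes and these donors without it 518; which genes differed was not compared. With fry, which does not compare a list with other genes, 15 of 18 lists passed between the sites and dendritic cell maturation genes also passed in cervical Prevotella against Lactobacillus.

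The planned depth minimum of 0.2 of the site median removed 0 libraries and says nothing about stability. At a median of 59456 counts, genes with few counts could not be compared, and in the simulated cervical Prevotella comparison most 2-fold changes were missed.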

Other observations

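The comparison of both communities together with Lactobacillus and the tests of counts at an unadjusted p were chosen after the separate comparisons were seen, and the other splits in this part were planned.

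Gardnerella and Prevotella cervical libraries as 1 group (n = 13) had more IL6 (log2 fold change 2.95 ± 0.54, edgeR adjusted p = 0.0183) than the 5 Lactobacillus libraries. IL10 (3.00 ± 0.65), MIR155HG (2.76 ± 0.61) and IL1B (1.79 ± 0.41) also rose and the ribosomal protein gene RPLP2 fell (-2.48 ± 0.55), each with an adjusted p of 0.0416. These were the 5 genes of 857 that passed, and 123 had an unadjusted p under 0.05. SERPINB9 (1.33 ± 0.32) and THBS1 (2.41 ± 0.58) followed with an adjusted p of 0.0520. Of 100 splits of the libraries, 3 gave as many genes (highest other 8), which does not allow for a grouping chosen after the results. RPLP2 ran from 317 to 4856 CPM among the Lactobacillus libraries.

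In blood the same comparison gave 0 genes of 746 in edgeR, with 95 at an unadjusted p under 0.05, and no other tool was run on it. HLA-DRB1 (-1.67 ± 0.37), HLA-DPB1 (-1.60 ± 0.36) and RFC1 (-1.63 ± 0.36) had the smallest adjusted p, 0.0640. A count of 0, which all 100 splits reach (highest other 4), says nothing about chance.

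For cervical Gardnerella against Lactobacillus, 2 of 100 splits, the real one included, gave as many genes (1, highest other 1). There 1, 1 and 2 splits gave as large a value for NF-kB targets (2.26, highest other 1.96), cytokines (2.65 and 2.48) and anti-inflammatory regulators (2.79 and 2.86). Splits rarely reached these values. Chance is not excluded by this, since only lists that had passed were split and 7 of 13 fits without 1 library gave 0 genes. For cervix against blood 1 of 100 splits, the real one, gave as many genes (593, highest other 205), which argues against chance. All of these splits, like the real one, parted the 12 pairs of libraries of 1 donor.

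The other comparisons had 0 genes, which every split reaches (100 of 100, or 35 of 35 for blood Prevotella against Lactobacillus), so these counts say nothing about chance. The highest other splits gave 42 genes for cervical Prevotella against Gardnerella, 1 for blood Gardnerella against Lactobacillus, 39 for blood Prevotella against Gardnerella and 0 for blood Prevotella against Lactobacillus. Splits with 42 and 39 genes point to a structure of the samples, whose origin was not tested. By genes at an unadjusted p under 0.05 in edgeR, chance could not be excluded in the first 3, where 100, 16 and 14 of 100 splits gave as many (5, 38 and 65, highest others 177, 65 and 150). For blood Prevotella against Lactobacillus 1 of 35 splits, the real one, did (131, highest other 86). This does not exclude chance, since 35 splits allow no smaller count and the measure was chosen after the results. In the same order DESeq2 called 0, 0, 0 and 18 genes, and limma with quality weights 0 in each.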
